A study of Mus musculus with 2 samples.

How the data were processed

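H3K27me3 was measured by ChIP-seq in liver of newborn mice (postnatal day 0) of the strain named B6NTac;B6NCrl/Lap in the labels. The 2 biological replicates were numbered 1 and 2 as in the labels. Each combined 2 technical replicates and used DNA fragments of 300 to 500 bp, per the labels. The labels name the same experiment as the possible control of both replicates. The labels describe both samples as pools of male and female mice, without the number of each sex.

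The authors deposited peak lists in the narrowPeak format with coordinates on the mouse build mm10, per the labels and the text files beside the data. Each replicate's own list was called on the alignments of that replicate with 2 further files that both replicates used, and the pooled list was called on the alignments of both replicates with the same 2 files, per these text files. The content of the 2 files, the aligner, the read filters, the peak caller and its version were not given in the sources used here. Neither was the rule by which the authors kept a pooled peak in the replicated list. A comparison of the rows showed that all 24949 replicated peaks are rows of the pooled list, of which they make up 58.1%. For each peak the authors deposited a fold enrichment, read here as a ratio over background, and the −log10 of a p-value. The values are per peak as the caller gave them, were not scaled between lists by any step recorded in the sources, and were used here to describe, rank and filter peaks within a list. They were also set side by side between the replicates' own lists, in the correlation across shared peaks and in the mean ± SD of the fold at named genes, so these means and SDs include any difference in scale between the lists. The lowest −log10 p was just above 2 in every list, from 2.03 to 2.06, which corresponds to a threshold near 0.01. The −log10 q-values and summit positions were not used here. Signal tracks named in the text files were not analysed here. Counts of reads were not analysed here either, so depth was unknown, no detection limit was set, and a difference in depth between the replicates could change the number of peaks.

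Genes were taken from GENCODE mouse release M21 on GRCm38, the assembly that mm10 denotes. No peak ran past a chromosome end of this assembly. Coordinates are given 1-based. The 5′ end is that of the gene record, with 21938 protein-coding genes on chromosomes 1 to 19, X and Y. A promoter was marked when a peak overlapped by at least 1 bp the window of 1 kb either side of the 5′ end. The main calls used the replicated list. Kilobases covered within 5 kb and the highest fold of any peak touching the 1 kb window were computed from each replicate's own list and are given as mean ± SD over n = 2. The replicates are separate pools, per the labels, and the SD covers the spread between these pools.

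Overlap of the replicates used a minimum of 1 bp. Random expectations came from 100 placements of the peaks at random positions on their own chromosome outside assembly gaps of 100 bp or more, and the smallest p these allow is 0.0099 one-sided and 0.0198 two-sided. Peak midpoints were assigned in the order promoter, exon, intron, intergenic. Discordant promoters were tested with a two-sided exact binomial test over genes, which compares these 2 lists and takes no account of the spread between pools. Each of 21 gene lists was compared with all other coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 21 lists and a threshold of 0.05. Intervals of shares are 95% exact binomial intervals over genes. Domains were built by joining replicated peaks across gaps of up to 3 kb.

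The lists, tests, settings and the rule for named genes were fixed before the data were examined. The lists covered 5 groups of developmental regulators, hepatocyte transcription factors and hepatocyte genes of birth and of later life, blood, endothelial, stellate and biliary cells, neuronal and muscle effectors, pluripotency, housekeeping, cell cycle, Polycomb and imprinted genes. Of 856 symbols, 10 matched no coding gene and 2 were older symbols of a gene already in the same list, which left 844 list memberships. Noncoding members such as H19 and Meg3 were left out of the tests. The lists hold 829 different genes, 15 of them in more than 1 list, so the tests are not fully independent. The rule named, for each list, up to 3 marked genes with the most kilobases covered within 5 kb, and all members that went against the majority of their list where these numbered 6 or fewer. It also named the coding genes of the 10 widest domains, the 10 coding genes outside the lists with the highest mean fold, and Alb, Afp, Cyp7a1, Cyp3a11, Hbb-bt, Gata1, Pdx1, Sox9, Cdkn2a, Hmga2, Igf2bp3 and Actb. Further members are named as examples of a list and were chosen after their values were seen. Values at near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and the Mup, Cyp2, Cyp3a, Ugt2b and Serpina1 families) are uncertain, because reads that map to several copies may have been removed before peak calling.

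The list test was tested on simulated marks over the 21938 genes in 20 runs, with 5 changed lists in each. At a true share of 80% all 100 changed lists were recovered, and at 50% 84 of 100 were. At 20%, the share drawn for the other genes, 0 of 100 were called higher. No share between 20% and 50% was simulated. Of the unchanged lists, 2.92% were called in the runs at 80%, 0.893% in those at 50% and 0.439% in those at 20%. Marks were drawn independently for each gene, so these rates do not cover a mark that spans neighbouring genes. No share below that of the other genes was simulated. Alternatives changed the promoter window to 0.5 kb or 2 kb, required 500 bp of cover, used the pooled list, the intersection of the replicates, the stronger 0.5 of the peaks by −log10 p, lists of equal length, or each replicate alone. They also used 10000 random lists matched on the CpG observed-to-expected ratio in deciles, or 1 gene per run of 5′ ends within 50 kb. Leaving out the X chromosome was added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.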

Results

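Trimethylation of histone H3 at lysine 27 (H3K27me3), the chromatin mark deposited by Polycomb repressive complex PRC2, was mapped by chromatin immunoprecipitation and sequencing in whole mouse liver on the day of birth. Newborn liver holds hepatocytes beside blood-forming, endothelial, stellate and biliary cells, so a peak reports the mark in an unstated share of the tissue. The single group consisted of 2 biological replicates, each a pool of male and female livers. The pool of replicate 1 came from 15 mice, and the size of the pool of replicate 2 was not given in the sources used here. Peaks were analysed in 4 lists. The list of replicate 1 held 76600 peaks and that of replicate 2 held 56985 peaks. A list called on both replicates together held 42913 peaks, and a replicated list held 24949 peaks, all of them rows of the pooled list. Read depth was unknown for all lists, so a missing peak shows only that none was listed. With a single group there was no treated or control condition to compare, and the comparisons below set the replicates against each other and gene groups against all other coding genes.

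The replicates' own lists shared 4406 marked promoters, among them those of all 39 Hox genes, while most single peaks of replicate 1 had no partner in replicate 2. Peaks of replicate 2 touched 28314 of the 76600 replicate 1 peaks, or 37.0%, against 2.08% when the replicate 2 peaks were placed at random on the same chromosomes. In the other direction, 30079 peaks of replicate 2, or 52.8%, touched a replicate 1 peak, against 2.47% at random. The bases shared by both lists made up a fraction of 0.371 of the bases covered by either list, against 0.00628 at random. All 3 measures exceeded the highest of 100 random placements (one-sided permutation p = 0.0099, the smallest these placements can give). Across the 28314 shared peaks, the fold enrichments given by the authors' peak caller correlated between replicates with Spearman's rho = 0.548 and Pearson's r = 0.632. This correlation is across peaks, which are not independent replicates. Of the replicated peaks, 88.4% were touched by peaks in both replicates' own lists.

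The mark lay preferentially at promoters and exons. In the replicated list, 18.5% of peak midpoints fell within 1 kb of the annotated 5′ end of a coding gene, against 1.73% ± 0.0817 (SD over 100 random placements), a ratio of 10.7. Exons held 8.75% of midpoints, 2.44 times the random share. Introns held 32.7%, or 0.882 times the random share, and intergenic sequence held 40.0%, or 0.695 times. Each of the 4 shares lay outside the random range (two-sided permutation p = 0.0198, the smallest possible). The promoter ratio was 5.96 in replicate 1's own list and 7.29 in replicate 2's, and the intron ratio of 0.992 in replicate 1's list lay within the random range (permutation p = 0.0792).

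A promoter was counted as marked when a peak touched the 2 kb window centred on the 5′ end of the gene. The replicated list marked 4337 of 21938 coding genes (19.8%). The replicates' own lists marked 5290 and 4906 genes, and 4406 genes were marked in both, which is 76.1% of those marked in either. Replicate 1 alone marked 884 genes and replicate 2 alone marked 500, so 63.9% of the discordant genes were in replicate 1 (two-sided exact binomial p = 3.69e-25). This test compares the 2 lists over genes, which are not replicates, and the longer list of replicate 1 favours an excess there. On the X chromosome the discordant genes numbered 204 in replicate 1 and 7 in replicate 2, and elsewhere they numbered 680 and 493. With 56985 peaks taken from each list by −log10 p, 50.8% of the discordant genes were in replicate 1 (exact binomial p = 0.596).

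Developmental transcription factors carried the mark in most cases. All 39 Hox genes, which set position along the body axis, were marked in the replicated list and in both replicates' own lists. Of 64 neural and sensory transcription factors, 63 were marked, among them Olig2, Lhx1 and Emx2. The exception was Neurod6, where a peak covered 195 bp of the window in replicate 2 and none did in replicate 1. Of 57 transcription factors of mesoderm, limb and skeleton, 50 were marked, including Pax9, Msx1 and Evx1. Other endoderm and kidney factors were marked in 28 of 30 cases. Among them were the intestinal factor Cdx2, the pancreatic factor Pdx1, the kidney and gonad factor Wt1 and the gut factor Nkx2-3. Wt1 and the marked factors Hnf1b and Gata4 are also in the stellate, biliary and endothelial lists, in that order. The unmarked members were Foxi1 and Foxn1. At Foxn1 a peak covered 195 bp of the window in replicate 2 and none did in replicate 1. Developmental signalling ligands and antagonists were marked in 55 of 63 cases, including Wnt10a, Gdf7 and Wnt10b. The share among all other coding genes was between 19.5% and 19.7% for these 5 lists, and each list exceeded it (Fisher's exact test, Benjamini-Hochberg adjusted over 21 lists, adjusted p between 3.35e-42 and 2.17e-17). The replicates' own lists gave 99.2% ± 1.10 (SD, n = 2) for the neural list and 90.4% ± 3.72 (SD, n = 2) for the mesoderm list. The endoderm and kidney list gave 95% ± 2.36 and the signalling list 88.1% ± 1.12 (SD, n = 2).

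Peak widths differed among these genes. Within 5 kb either side of the Olig2 5′ end (chr16, position 91225457), peaks covered the whole window in both replicates, and the replicated peak ran from 91218727 to 91235231. At Emx2 the replicated peak ran from 59450519 to 59472629 on chr19, a width of 22111 bp. Its strongest promoter peak had a fold enrichment of 10.3 ± 0.511 (SD, n = 2). Pdx1 had 8.29 kb ± 0.0629 covered (SD, n = 2) and a replicated peak from 147269650 to 147275323 on chr5, with its midpoint in an intron. At the signalling gene Wnt10a the replicated peak ran from 74788603 to 74792668 on chr1, a width of 4066 bp. Its midpoint lay outside coding genes. At Neurod6, 1.40 kb ± 0.302 was covered within 5 kb (SD, n = 2).

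**Figure D1:**
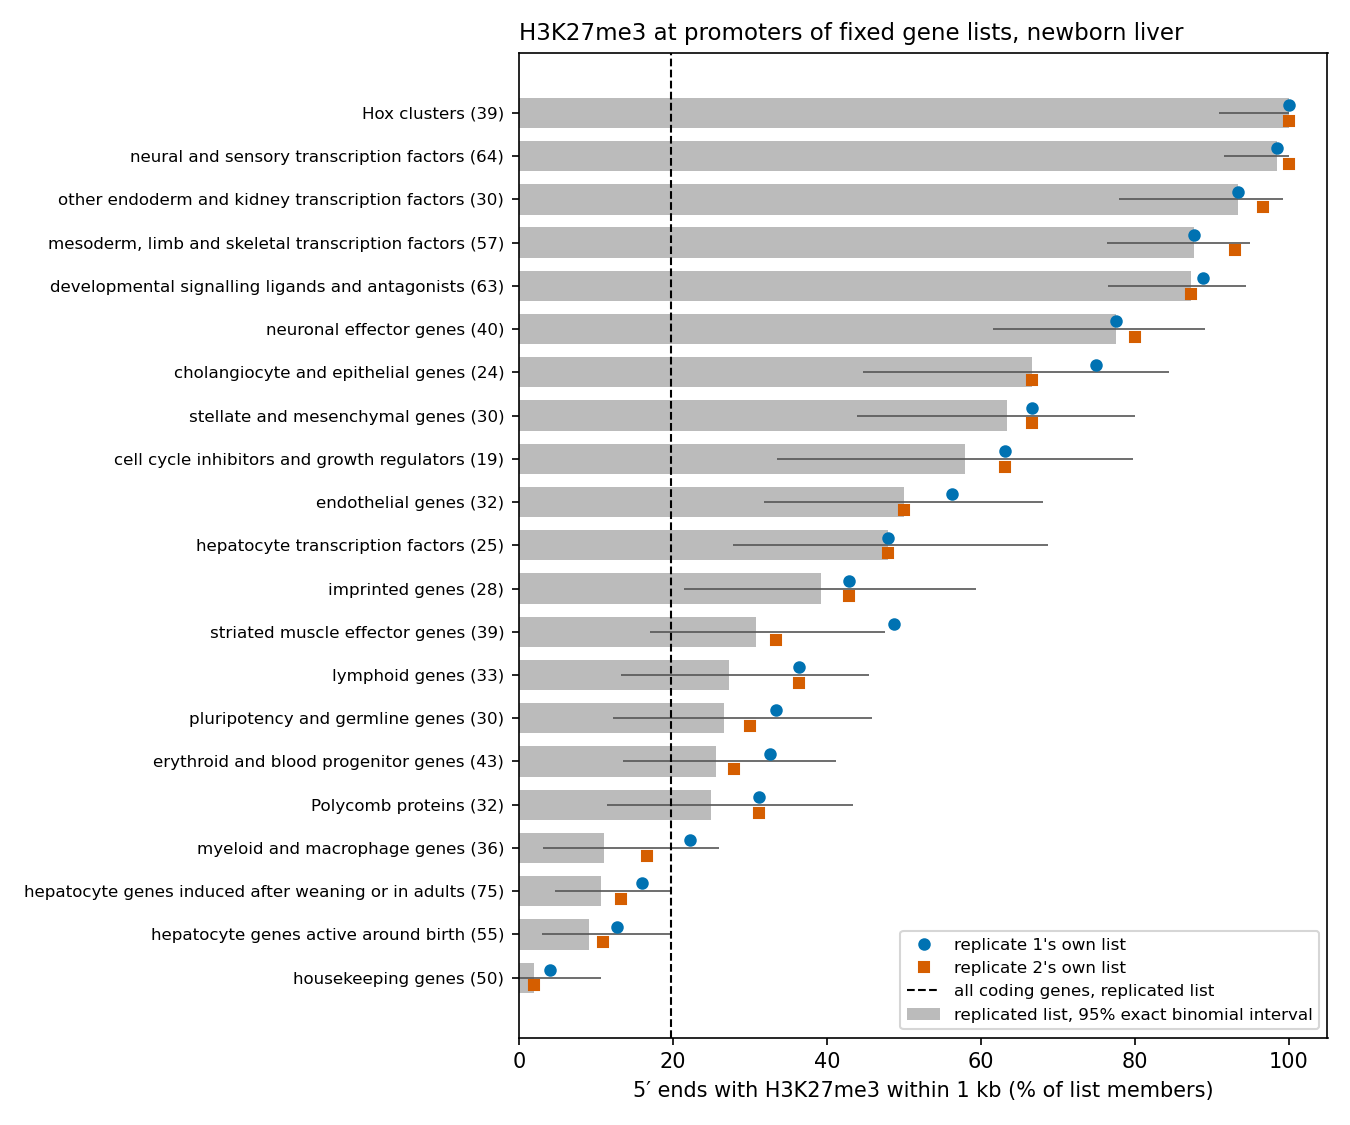
Share of each fixed gene list with H3K27me3 within 1 kb of the 5′ end (% of members, number of members in parentheses); grey bars give the replicated list with 95% exact binomial intervals, circles replicate 1's own list, squares replicate 2's own list, and the dashed line all coding genes (19.8%). The Hox bar reaches 100% and the housekeeping bar 2.0%, and both hepatocyte gene lists lie left of the dashed line.

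Among hepatocyte transcription factors, 12 of 25 were marked in the replicated list and in each replicate's own list (48.0%, adjusted p = 0.00241, Fisher's exact test). The marked members included Foxa1, Foxa2, Foxa3, Cebpa, Onecut1, Prox1 and the nuclear receptor gene Ppara. Unmarked members included Hnf1a and the nuclear receptor genes Hnf4a, Nr1h4, Nr1i2 and Nr1i3. At Foxa1 (5′ end at 57546916 on chr12), 8.05 kb ± 0.0615 was covered within 5 kb, and the fold enrichment was 6.00 ± 0.374 (SD, n = 2). The strongest replicated peak to touch its promoter window ran from 57547913 to 57551481, on the upstream side of this minus-strand gene. Its midpoint lay outside coding genes. This peak reached only the edge of the window, in which replicated peaks covered 1533 bp, so most of that cover came from elsewhere in the list. Onecut1 had 7.91 kb ± 0.111 covered (SD, n = 2), with the replicated peak midpoint in an exon. Tbx3, which this list shares with the mesoderm list, had 7.59 kb ± 1.00 covered (SD, n = 2).

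Genes that hepatocytes express around birth were rarely marked, and so were hepatocyte genes induced only after weaning. Of 55 genes active around birth, 5 were marked (9.09%), namely Igf2, Dlk1, Gpc3, Rbp4 and Apoh. Igf2, Dlk1 and Gpc3 are fetal growth genes. The 5′ end of another coding gene, Prkca, lay within 2 kb of that of Apoh. Neither replicate had a peak within 5 kb of the 5′ ends of Alb and Afp, which encode albumin and alpha-fetoprotein. Of 75 genes induced after weaning or in adults, 8 were marked (10.7%): Car3, Cyp26a1, Elovl3, Gls2, Rhbg, Sds, Slc1a2 and Susd4. Cyp26a1, which degrades retinoic acid, had the broadest mark of these, at 8.34 kb ± 0.339 within 5 kb and a fold enrichment of 8.79 ± 2.25 (SD, n = 2). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and the adult drug-metabolising enzyme Cyp3a11 had no peak within 5 kb in either replicate. Neither list passed the test against the other coding genes (adjusted p = 0.0838 for each, Fisher's exact test). No difference between adult genes and birth genes was detected, with an odds ratio of 1.19 (95% interval 0.321 to 4.92, Fisher's exact p = 1). The interval allows differences of several fold in either direction. By Fisher's exact test, both lists stood below the other genes with the pooled list (adjusted p = 0.0298 for birth and 0.0470 for adult genes). They also did so with 1 gene counted per 50 kb (adjusted p = 0.0363 and 0.00552, Fisher's exact test). With that count the lists stood slightly higher than in the main test, at 11.6% and 11.4%. The share of the other genes was 26.7% there, against 19.8% in the main test. Against random lists matched for CpG content neither passed (adjusted permutation p = 0.982 and 0.340).

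None of the 3 blood cell lists passed the test against the other coding genes. The erythroid and progenitor list was marked in 11 of 43 cases (25.6%, adjusted p = 0.374, Fisher's exact test). Its marked members were the progenitor genes Gata2, Kit, Tal1, Myb, Cd34, Hlf and Bcl11a and the erythroid genes Ank1, Epor, Sptb and Gfi1b. Other progenitor genes (Runx1, Meis1, Mecom, Lmo2, Lyl1 and Mpl) and other erythroid genes (Gata1, Klf1 and the globin genes Hba-a1, Hba-a2, Hbb-bt and Hbb-bs) were unmarked, and no split within the list was tested. At Gata2, peaks covered 9.81 kb ± 0.0417 within 5 kb (SD, n = 2), and the replicated peak ran from 88192539 to 88202940 on chr6. Myeloid genes were marked in 4 of 36 cases (11.1%, adjusted p = 0.341, Fisher's exact test), namely Mafb, Cd14, Irf8 and Prtn3. The replicates' own lists marked 8 and 6 of the 36. The 5′ end of Plppr3 lay within 2 kb of that of Prtn3. Lymphoid genes were marked in 9 of 33 cases (27.3%, adjusted p = 0.341, Fisher's exact test), among them the transcription factor genes Pax5, Ebf1, Gata3 and Bcl11b and the surface protein genes Cd3e and Thy1. The transcription factor genes Foxp3 and Rorc were unmarked. The 5′ end of 9230102O04Rik lay within 2 kb of that of Gata3. Against random lists matched for CpG content the erythroid list did stand higher (25.6% against 12.7%, adjusted permutation p = 0.0297, 10000 random lists).

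The lists for other cells of the liver were marked more often than other genes. Cholangiocyte and epithelial genes were marked in 16 of 24 cases (66.7%). These included the biliary regulator Sox9, the epithelial factor Grhl2 and the adhesion genes Epcam and Cdh1, while Krt19, Krt7, Krt23, Spp1 and Pkhd1 were unmarked. Stellate and mesenchymal genes were marked in 19 of 30 cases (63.3%), among them Pdgfra, Lhx2, Col1a1 and Col1a2, while Acta2, Col3a1 and Dcn were unmarked. Endothelial genes were marked in 16 of 32 cases , including Sox7, Dll4, Hey2, Kdr and Flt1, while Pecam1, Cdh5, Tek and Stab2 were unmarked. The adjusted p-values were 2.00e-06, 6.88e-07 and 2.87e-04 in that order (Fisher's exact test). At Pdgfra, a receptor of mesenchymal cells, 9.12 kb ± 0.524 was covered (SD, n = 2), and the replicated peak ran from 75147686 to 75155340 on chr5. The 3 lists share members with the transcription factor lists, among them Wt1, Hand2, Lhx2, Sox9, Hnf1b, Onecut1 and Gata4.

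Neuronal effector genes were marked in 31 of 40 cases (77.5%, adjusted p = 1.97e-14, Fisher's exact test). Pcdh8 had the strongest mean fold of the 3 broadest, at 11.3 ± 0.644 (SD, n = 2), beside the GABA transporter gene Slc32a1 and the GABA-synthesising enzyme gene Gad2. Striated muscle effector genes were marked in 12 of 39 cases (30.8%, adjusted p = 0.137, Fisher's exact test), including Myl3, Acta1 and Cacna1s. The 5′ end of Ascl5 lay within 2 kb of that of Cacna1s, where the strongest replicated peak had its midpoint outside coding genes. The muscle list was the one in which the replicates differed most, with 48.7% marked in replicate 1 and 33.3% in replicate 2. By Fisher's exact test it passed the threshold with replicate 1's own list (adjusted p = 0.00176) and with the pooled list (0.0294), and it also passed against CpG-matched random lists (permutation, 0.0145). Pluripotency and germline genes were marked in 8 of 30 cases (26.7%, adjusted p = 0.376, Fisher's exact test), among them Utf1, Lin28a and Pou5f1, but not Nanog, Dazl or Ddx4.

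Housekeeping genes formed the only list that passed the main test as lower than the other genes. In this list 1 of 50 genes was marked (2.0% against 19.8%, adjusted p = 9.24e-04, Fisher's exact test). That gene was the ribosomal protein gene Rpl3, whose 5′ end lies within 2 kb of that of Syngr1, so the peak cannot be assigned to either gene. Replicate 1's own list marked 2 of the 50. Actb had no peak within 5 kb in either replicate. Cell cycle inhibitors and growth regulators were marked in 11 of 19 cases (57.9%, adjusted p = 5.80e-04, Fisher's exact test). They included the cell cycle inhibitor genes Cdkn2a, Cdkn2b and Cdkn1c, the cyclin genes Ccnd1 and Ccnd2, and the fetal growth gene Hmga2. The inhibitor genes Cdkn1a, Cdkn1b, Cdkn2c and Cdkn2d were unmarked. The Cdkn2a values are for the 5′ end of the gene record and were not computed for the start of the p16 transcript. Cdkn2a had 7.68 kb ± 0.370 covered, and Hmga2 had 3.99 kb ± 0.981 (SD, n = 2), while Igf2bp3 had no peak within 5 kb. Genes for Polycomb proteins themselves were marked in 8 of 32 cases (25.0%, adjusted p = 0.503, Fisher's exact test), with Cbx8, Cbx4 and Bmi1 the broadest. Imprinted coding genes were marked in 11 of 28 cases (39.3%, adjusted p = 0.0253, Fisher's exact test), including Grb10, Ascl2, Dlk1 and Igf2. The call for imprinted genes was lost in 5 of 11 alternatives, with adjusted p between 0.0523 and 0.107 in those.

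Joined across gaps of up to 3 kb, the replicated peaks formed 9544 domains, of which 644 were at least 10 kb wide. The 4 widest lay at the Hox clusters. The HoxC domain ran from 102894166 to 103071655 on chr15, spanned 177 kb and held the 5′ ends of 9 coding genes. Peaks covered 81.9% ± 1.67 of it (SD, n = 2). The HoxA, HoxB and HoxD domains spanned 139 kb, 137 kb and 122 kb, and the HoxD domain also held Evx2. Peaks covered 81.4% ± 1.10, 77.3% ± 4.68 and 88.8% ± 1.33 of them (SD, n = 2). The next 6 domains spanned 66.5 to 88.0 kb. They held Mcf2l on chr8, the gut factor gene Nkx2-3 on chr19, and Zic1 and Zic4 on chr9. Among them, 3 held no coding 5′ end and lay nearest to Mylip on chr13, Polg on chr7 and Smug1 on chr15. The domain nearest to Smug1 began at 103081230, close to the end of the HoxC domain. Replicated peaks between 103074687 and 103077648 lay between these 2 domains, so their separation depends on the joining gap. Domains of at least 10 kb held 609 coding 5′ ends, or 2.78% of all. They held all 39 Hox genes, 85.9% of the neural, 73.7% of the mesoderm and 70.0% of the endoderm and kidney transcription factors, but 30.2% of the signalling genes and 12.5% of the neuronal effector genes. The number of such domains was 1365 with replicate 1's own list and 923 with replicate 2's, and 392 or 1140 with joining gaps of 1 kb or 10 kb.

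**Figure D2:**
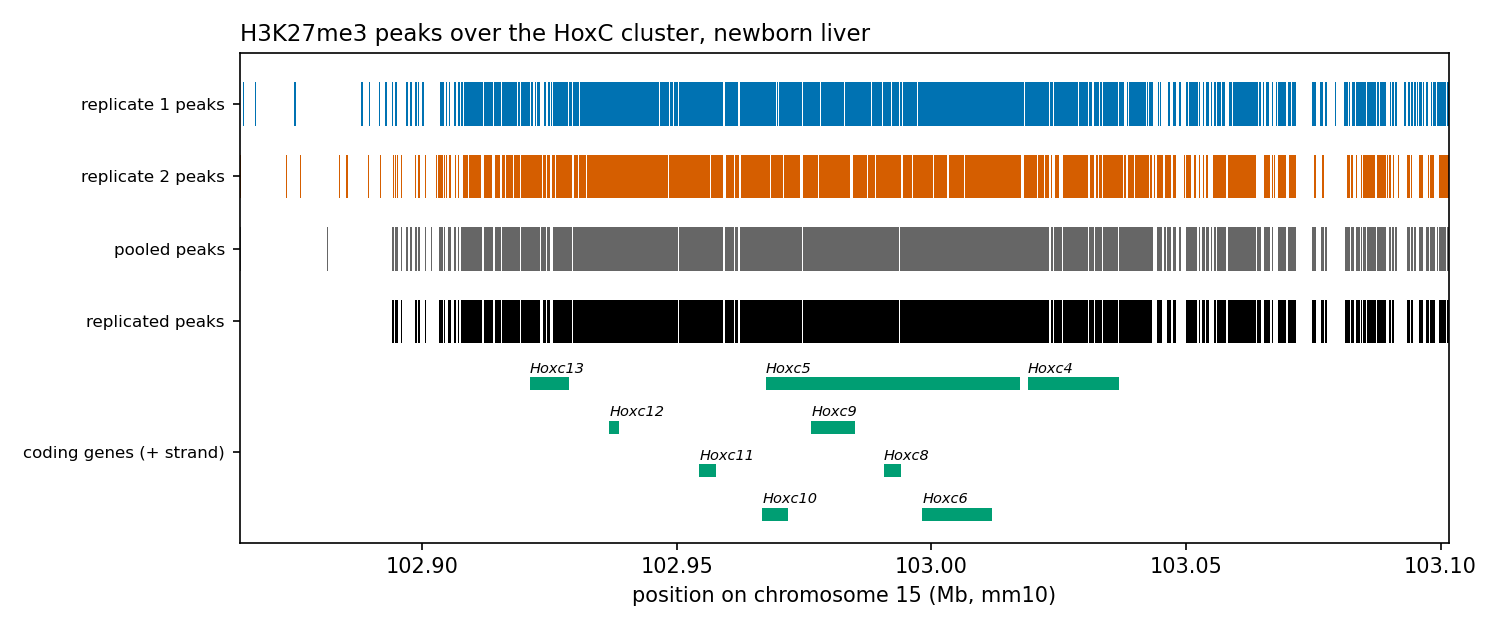
Map of 237 kb of chr15 (mm10, position in Mb) with the HoxC cluster; boxes mark the peaks of replicate 1, replicate 2, the pooled list and the replicated list, and the 9 coding genes, all on the plus strand. In all 4 lists nearly continuous peaks span the region from Hoxc13 to Hoxc4.

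Outside the fixed lists, marked coding genes were ranked by the mean over both replicates of the strongest fold enrichment at the promoter, a scale that was not equalised between the lists. The highest means were at the homeobox gene Hmx3 (12.1 ± 0.207), the cytokine receptor-like gene Crlf1 (12.0 ± 0.0392) and Egr3 (11.5 ± 0.326; all SD, n = 2). The cartilage matrix gene Comp (11.5 ± 0.714), the pacemaker channel gene Hcn2 (11.4 ± 0.0320) and Ccdc177 (11.3 ± 1.07) followed. Ebf3 (11.3 ± 1.05), Pou3f1 (11.2 ± 4.62), Pou2f2 (11.2 ± 0.0312) and C1ql1 (11.2 ± 0.827) completed the highest 10. Of these 10 the SD was largest at Pou3f1, with 7.98 in replicate 1 and 14.5 in replicate 2. The Crlf1 peak in the replicated list ran from 70485268 to 70497682 on chr8, and the Hmx3 peak from 131540218 to 131544900 on chr7.

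The replicates differed most on the X chromosome. Replicate 1 had 12629 X chromosome peaks and replicate 2 had 1705, a ratio of 7.41, while the ratio on the 19 autosomes lay between 1.10 and 1.21. Peaks of replicate 1 covered 2.32% of the X and 1.28% of the autosomes, and those of replicate 2 covered 0.313% and 1.09%. The coverage of the X relative to the autosomes was 1.81 in replicate 1 and 0.287 in replicate 2, with 0.337 in the replicated list. The median fold enrichment of X chromosome peaks was 3.13 in both replicates, and their median widths were 250 bp and 230 bp. No list held a peak on the Y chromosome. With 1 pool on each side, no test of the difference between pools was run. Without X chromosome genes the same 12 lists were higher, the housekeeping list was lower, and the hepatocyte genes active around birth also passed as lower (adjusted p = 0.0350, Fisher's exact test).

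**Figure D3:**
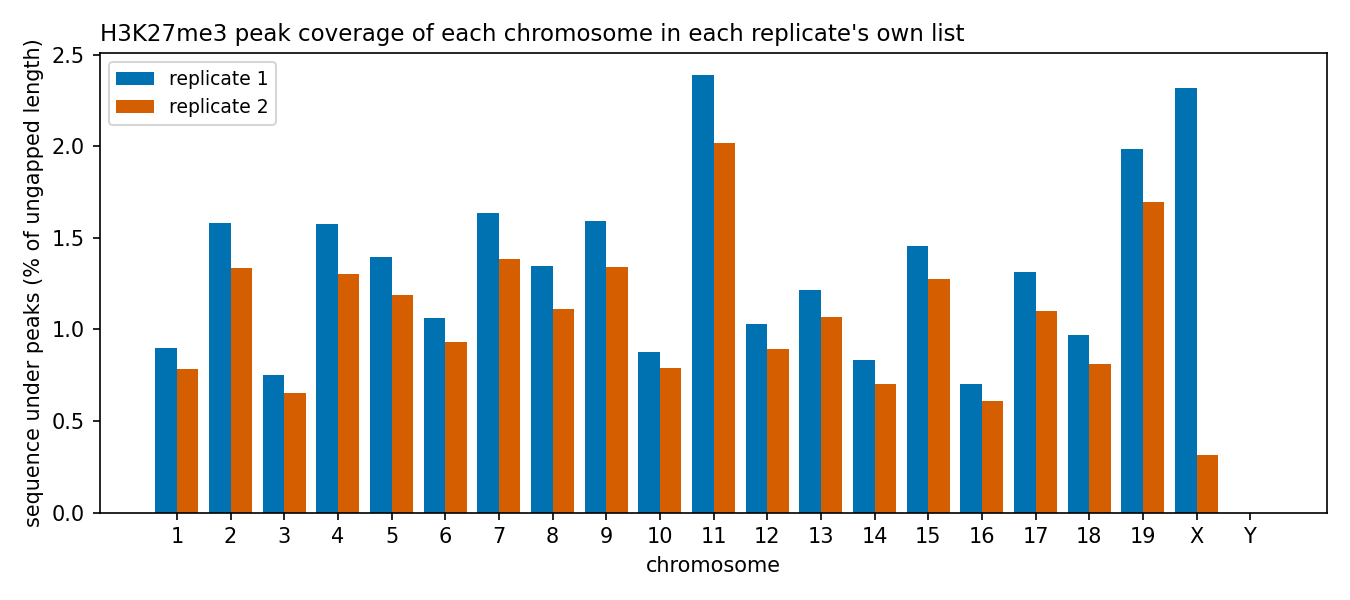
Share of the ungapped length of each chromosome under H3K27me3 peaks (%) in the own list of replicate 1 (blue) and replicate 2 (orange), with 1 bar per chromosome and replicate. The bars are close on every autosome, while on the X they stand at 2.32% and 0.313%.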

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

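The noncoding and pooled-list counts, and the comparison of the X chromosome ratio with the autosomes, were chosen after the values were seen, and the other tests of explanations were set before their results were seen.

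Away from coding promoters, 443 of 7550 long noncoding RNA genes (5.87%) had a replicated peak within 1 kb of the 5′ end. They lie more than 5 kb from any coding 5′ end and enter no comparison of the report. Within 5 kb of a coding 5′ end the share was 28.8% (592 of 2055), and among coding genes it was 19.8%. No random expectation was computed, so the 5.87% cannot be told apart from background or from broad domains that reach these genes. The pooled list held 1900 X chromosome peaks that the replicated list left out, of 17964 such peaks in all.

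Replicate 1 had 7.41 times as many X chromosome peaks as replicate 2. Deeper or more lenient calling that raised all chromosomes alike would give the X a ratio near the autosomal ones. The highest autosomal ratio was 1.21. Depth was unknown, so calling that adds more peaks where weak signal is common is not excluded. Extra X chromosome DNA without a change in the mark was predicted to cover gene bodies evenly, an assumption that was not checked. In replicate 1 the bodies of 44 active X genes subject to X inactivation were covered to 2.83% ± 2.90 (SD over genes). Those of 11 genes listed as escaping it were covered to 0.847% ± 1.96. The difference was 1.98 percentage points (two-sided permutation p = 0.0174, 100000 resamples). The mark of the inactive X in a pool with more female cells predicts this difference and also remains open as an explanation. The sex ratio of neither pool is given.

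In replicate 1, 35 of the 44 active X genes and 3 of the 11 escape genes (Mid1, Utp14a and Jpx) held any peak. In replicate 2 the means were 0.137% and 0.220% (permutation p = 0.627). The active X genes were covered more than 47 autosomal housekeeping genes in both replicates, at 2.83% against 0.0508% in replicate 1 (permutation p = 2.00e-05, the smallest possible) and at 0.137% against 0% in replicate 2 (permutation p = 0.00972). More X chromosome DNA alone would also raise X genes over autosomal genes, so this comparison does not separate the explanations. Both gene sets were written from general knowledge before the test, and their length and expression were not matched. The escape set includes Xist, a noncoding gene of the inactivation process itself, and the noncoding genes were not tested apart. No peak lay in the body of Xist in either replicate.

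The developmental lists were marked far more often than other genes. CpG-rich promoters attract Polycomb complexes in general, so lists of CpG-rich genes might stand high for that reason alone. Still, 11 of the 12 higher lists stayed higher than random lists matched on CpG ratio. The matching used deciles of this ratio and not GC content, so the result speaks to this ratio only. The endothelial, stellate and neuronal effector lists had median ratios of 0.318, 0.437 and 0.435, below the 0.474 of all coding genes. Counting neighbouring genes separately could inflate clustered lists such as Hox, but with 1 gene per 50 kb 11 of the 12 lists again kept the call, with Hox reduced to 6 loci, all marked. For imprinted genes, which lost the call in both tests, both explanations stay open. Their excess was 19.5 percentage points in the main test, 17.2 points over CpG-matched lists (adjusted permutation p = 0.0701) and 18.4 points with 1 gene per locus (adjusted p = 0.107, Fisher's exact test), so the call ended with little change in the excess, at 28 and 20 genes.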

How the results depend on the processing

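No paired analysis was possible because there is a single group. Read depth, which limits how many weak peaks can be called, was unknown. Leaving out the X chromosome was chosen after seeing the data, and all other alternatives before. The overlap of the replicates exceeded random placement under every alternative, marked promoters numbered 3565 to 5290, and 11 to 13 lists stood higher, 11 or 12 of them among the 12 of the main test. The causes of the changes that follow were not tested, unless stated. The correlation across shared peaks was 0.611 with at least 0.5 of the peak covered, against 0.548. With lists of equal length, 50.8% of discordant promoters were in replicate 1, so that call was lost when the lists had the same length. Lower lists numbered 3 with the pooled list, 2 with the stronger 0.5 of the peaks, 3 with 1 gene per locus and 2 without the X chromosome, against 1. Domains of at least 10 kb numbered 392 with a gap of 1 kb and 1140 with a gap of 10 kb, which follows from the joining rule, and 923 to 1365 with single replicates, against 644. The intron ratio was 0.907 to 0.992 with single replicates. The coverage of the X relative to the autosomes was 0.287 to 1.81 with single replicates. The odds ratio of adult against birth hepatocyte genes was 0.981 with 1 gene per locus, against 1.19, and neither passed the test. Differences from other genes that changed sign without passing the test were those of adult hepatocyte genes (3.56 percentage points) and myeloid genes (3.50) against CpG-matched lists. Erythroid genes (-0.496) and Polycomb genes (-1.15) did so with 500 bp of cover, and Polycomb genes also against CpG-matched lists (-0.624) and with 1 gene per locus (-6.72). For single lists, 210 other comparisons kept direction and side of the threshold, 10 newly passed it and 5, all of imprinted genes, no longer did.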

Other observations

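All tests in this part were chosen after the data had been seen. Outside the fixed lists, coding genes were grouped by the letters that open their symbol, which gave 103 groups of at least 20 genes. These groups are naming conventions and only in part gene families. By Fisher's exact test with Benjamini-Hochberg adjustment over the 103 groups, 13 were marked more often than the other genes and 23 less often. Collagen genes stood highest, with 27 of 42 marked (64.3% against 18.5%, exact test, adjusted p = 2.47e-09). Cadherins were marked in 11 of 21 cases (exact test, adjusted p = 0.00378), regulators of G protein signalling (Rgs) in 11 of 22 (adjusted p = 0.00518), phosphodiesterases in 12 of 26 (adjusted p = 0.00703) and matrix metalloproteinases in 10 of 22 (adjusted p = 0.0161). G protein-coupled receptors with the symbol Gpr were marked in 30 of 73 cases (exact test, adjusted p = 2.07e-04) and solute carriers in 99 of 362 (27.3%, adjusted p = 5.24e-04).

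Of 1135 olfactory receptor genes, 2 were marked (adjusted p = 8.84e-99), and of 331 vomeronasal receptor genes none was (adjusted p = 6.69e-29, Fisher's exact test). Beta-defensins (0 of 42), taste receptors (0 of 38) and keratin-associated proteins (1 of 57) were also lower (exact test, adjusted p = 0.00207, 0.00395 and 0.00207). None of 46 Rpl and none of 49 Mrpl ribosomal protein genes outside the lists was marked (exact test, adjusted p = 0.00171 and 7.16e-04), nor was any of 35 Vps genes (adjusted p = 0.00795), and 1 of 67 histone genes was (adjusted p = 3.77e-04). Rps genes did not pass (2 of 38, exact test, adjusted p = 0.0790), nor did Eif genes (4 of 55, adjusted p = 0.0790), Cox genes (1 of 26, adjusted p = 0.141) or Polr genes (2 of 27, adjusted p = 0.336). Sec genes (1 of 29) and Med genes (1 of 30) did not pass either (exact test, adjusted p = 0.0757 for each). At a spacing of 50 kb, the olfactory receptor genes form 159 loci, the vomeronasal receptor genes 176, the beta-defensins 9, the taste receptors 14, the keratin-associated proteins 14 and the histone genes 8. Members of these groups are not independent, and their p-values are too small. None of the groups was matched on CpG content, so the scan does not separate group membership from the CpG content of the promoters. Cyp genes outside the lists did not pass (9 of 64, exact test, adjusted p = 0.573).

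The noncoding transcripts of the Hox clusters examined, Hotair, Hotairm1, Hottip, Hoxa11os and Hoxb5os, carried the mark in both replicates and in the replicated list. Their 5′ ends lie inside the HoxA, HoxB and HoxC domains described above, so these calls restate the marking of those domains. Among imprinted noncoding genes, Meg3 was marked in both replicates, while H19, Rian, Mirg, Airn, Kcnq1ot1 and Nespas were not marked in any of the 3 lists. Xist, Malat1 and Neat1 were not marked either.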
